A study of Homo sapiens with 2 samples.

How the data were processed

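One array per group was hybridised with Hy5-labelled total RNA from K562 cells given control or ETO2 siRNA, per the labels' protocols, and the labels name 1 sample per condition. The scanner tables hold, per the file headers, the median foreground and median local background intensity of each of 3136 spots, as whole scanner units before any normalization. Background subtraction or scaling in the scanner software is not given in the sources used here. All spots carried the flag for good spots on both arrays. Each array held 1719 miRNA probes with 1 spot each, 8 of them naming more than 1 miRNA, 1248 blank spots, and control spots. Both arrays bear the same slide code, so both groups lie on 1 slide, but each group is a single array, and array and group cannot be told apart.

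The authors also deposited a table of processed intensity values for the same arrays. Set against the scanner values, each of its columns was a straight line of the foreground with an intercept of 27.3 for control siRNA and 24.9 for ETO2 siRNA, near the blank means, and the median of each column was 25.0. Its values are thus linear signals over the blank level scaled to a common median, and higher values mean brighter spots. The spot statistic behind them stays unknown, since dim values scattered about the line by 1.95 and 1.98 units. It gave 718 values for control siRNA and 686 for ETO2 siRNA, and was used as an alternative.

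From the scanner tables, foreground was corrected for local background with limma 3.58.1 in R 4.3.3 (normexp on all spots, offset 50), taken to log2 and quantile normalized over the miRNA probes. The offset draws dim values together, and quantile normalization gives miRNAs of equal rank the same value, so that several of the brightest have a difference of exactly 0. A miRNA was detected when its raw foreground passed the mean plus 2 SD of the blank spots after leaving out the top and bottom 5% of them. The limits were 30.8 units for control siRNA and 28.3 for ETO2 siRNA. Counts were taken over miRNAs detected on at least 1 array. The number of arrays limits the precision.

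No test across samples was run, because each group has 1 array. The spot error of a difference combines the SD of all blank spots with the pooled CV of the 8 spots of each of 2 spike controls, carried to the log2 scale. No miRNA probe was spotted more than once, so the spread between spots of one miRNA was not measured. The SD of the difference at blank spots was 0.08 on the log2 scale. Blank spots were background corrected but not quantile normalized. A list's median was given where at least 3 members were detected. It was placed among the medians of 10000 random lists of the same size, as a description of these arrays. The random lists were drawn from detected miRNAs within 5 bins of mean signal and were not matched on catalogue number.

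The 19 lists held 179 members in all, each matched to a probe by mature name. They covered erythroid miRNAs that rise or decline with maturation, the miR-232724 and miR-17~92 clusters, the let-7, miR-15/16, miR-29 and miR-30 families, myeloid, megakaryocytic, lymphoid, p53-induced, HOX-cluster and imprinted miRNAs, and markers of muscle, liver, neurons, epithelium and mesenchyme. The lists, the settings, the alternatives and the rule for named miRNAs were fixed before the data were examined, except where stated. The rule took the 12 largest differences in each direction among miRNAs detected on both arrays with the same sign under median scaling, up to 5 per direction detected on 1 array, at most 4 examples a list, 6 erythroid and myeloid miRNAs fixed by name, and the 5 brightest.

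The steps were tested on simulated arrays built from the real signals, blank SD and spike CV. In the comparison of ETO2 siRNA with control siRNA over 1719 simulated miRNAs, 50 each were raised or lowered 2-fold or 4-fold. All changed miRNAs were drawn from the 331 detected on both arrays, so most of that set changed at once. The chosen setting called 18.0% of those raised 4-fold and 10.0% of those lowered 4-fold, and 0 of 596 unchanged detected miRNAs. Blank subtraction called 32.0% of those raised 2-fold, 62.0% of those lowered 2-fold, 100.0% of those raised 4-fold and 82.0% of those lowered 4-fold, with 34.7% of the 596 unchanged, or 42.9% of the 483 of these that had a value. Of 200 simulated lists of 10 members with no shift, 4.0% lay outside the central 95% of random lists, and 100.0% of 200 lists of 10 shifted by 2 SD of the simulated differences lay above it. The simulated differences were drawn independently of each other. Smaller lists, smaller shifts and lists whose members move together were not simulated.

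Alternatives were median, 75th percentile and no scaling, cyclic loess, blank subtraction, normexp with offset 0, no background correction, the deposited processed values, other detection filters and limits, and fold thresholds of 1.5 and 3. Blank subtraction took the trimmed blank mean from each foreground and scaled the arrays on the medians of miRNAs detected on both. It replaced both normexp and quantile normalization, so its differences from the chosen setting reflect both changes. Scaling on the spike controls, the mean of a spot's pixels, and blank subtraction joined with a stricter filter were added after seeing the data. The array files name no genome build, so no coordinates are given; the RefSeq gene table of GRCh38.p14 served only to see which miRNA genes neighbour each other. Probe sequences were not used here. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.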

Results

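MicroRNAs (miRNAs), the short RNAs that pair with messenger RNAs and lower their output, were profiled in K562 cells, a human erythroleukaemia line that carries features of erythroid and megakaryocytic precursors. The cells were nucleofected at 0 h and again at 24 h with 240 pmol of a control siRNA or of an siRNA against ETO2 (CBFA2T3), a transcriptional corepressor that keeps erythroid genes low in immature cells. Total RNA of each transfection was labelled with Hy5 and hybridised to 1 array, so each group had 1 sample. The comparison asked which miRNAs differ in level when ETO2 is targeted. The array carries probes for miRNAs and not for the ETO2 messenger RNA, so the degree of knockdown was not measured here. With 1 array per group there was no replicate check and no test across samples, and every difference below describes these 2 arrays. A difference is the log2 signal with ETO2 siRNA minus that with control siRNA, and each error is a spot error, which covers the spread between spots within an array and not the spread between cultures.

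Of 1719 miRNA probes, 528 were detected with control siRNA and 511 with ETO2 siRNA. Both arrays detected 331 of them, and 708 were detected on at least 1 array. Blank spots averaged 27.01 scanner units with an SD of 1.87 on the control array and 24.63 with an SD of 1.82 on the ETO2 siRNA array. Most detected miRNAs were dim: 79.2% of them on the control array and 78.9% on the ETO2 siRNA array lay under 30 units above the blank mean. The limit was passed by 6.49% of the blank spots on the control array and by 5.53% on the other. miR-4454 was the brightest miRNA and took 53.6% of the summed signal over the blanks with control siRNA and 54.7% with ETO2 siRNA. It was followed by miR-1260b, miR-4286, miR-1280 and miR-4284. The difference was 0.00 for miR-4454, miR-1260b and miR-4286, −0.16 (spot error 0.12) for miR-1280 and 0.33 (spot error 0.13) for miR-4284. The first spike control averaged 6129 units over 8 spots with control siRNA and 6425 with ETO2 siRNA, and the second averaged 4163 and 4141, with a pooled spot CV of 6.15%.

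No detected miRNA was 2-fold higher and none was 2-fold lower with ETO2 siRNA. The largest difference belonged to miR-93, a member of the miR-106b~25 cluster and of the miR-17 seed family, at 1.53-fold lower (difference −0.62, spot error 0.11). It read 352 scanner units with control siRNA and 230 with ETO2 siRNA. After it came miR-18b (difference −0.47, spot error 0.10), miR-103a (−0.39, spot error 0.09), miR-16 (−0.37, spot error 0.10) and miR-106b (−0.37, spot error 0.09). The other largest differences on the lower side were miR-19a, miR-18a, miR-142-3p, miR-223, miR-378g, miR-320d and miR-130b, from −0.36 for miR-19a to −0.26 for miR-130b. On the higher side stood miR-762 (difference 0.38, spot error 0.10), which read 166 units with control siRNA and 238 with ETO2 siRNA. It was followed by miR-3960, miR-4787-5p, miR-4530, miR-3665, miR-4739, miR-4284, miR-1469, miR-4745-5p, miR-4734 and miR-4281, between 0.36 for miR-3960 and 0.28 for miR-4281. The 12th miRNA on this side was miR-15b at 0.27 (spot error 0.08). Each of these 24 miRNAs was detected on both arrays and had the same sign under all 10 alternative settings tried. Both the detection and the sign under median scaling, which is among these settings, were conditions of their choice. All settings rework the same spots, so the shared sign is no replicate check. Among the 331 miRNAs detected on both arrays, 29 were lower and 34 were higher by more than 2 spot errors. Quantile normalization ties the 2 directions together, so these differences and counts are not independent. miR-19a and miR-3960 exchanged the same pair of normalized values, as did miR-18a and miR-4787-5p. Without normalization between arrays, these 4 stood at −0.27, 0.46, −0.33 and 0.40.

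**Figure D1:**
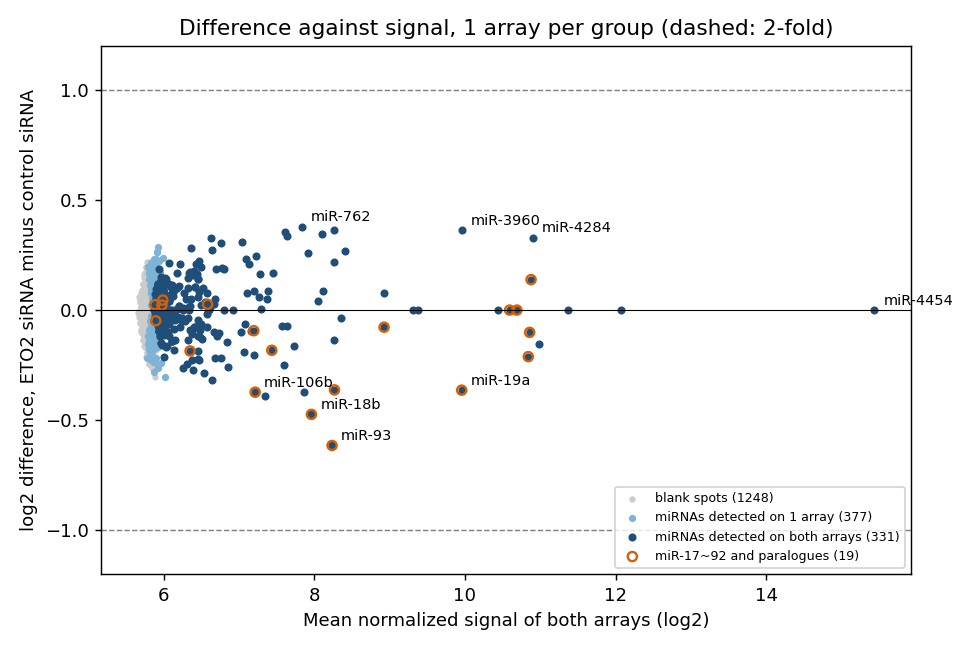
Difference between the arrays (log2, ETO2 siRNA minus control siRNA) against mean normalized signal (log2). Each point is 1 probe or blank spot, with 1 array per group and dashed lines at 2-fold. Blank spots were background corrected but not quantile normalized. All 708 detected miRNAs lie inside the dashed lines, miR-93 is the lowest at −0.62 and miR-762 the highest at 0.38, and miR-4454 lies at 0.00 because quantile normalization gives the same value to miRNAs of equal rank.

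The count of 0 holds for a setting that seldom called a 2-fold difference in the simulation. Of 50 simulated miRNAs raised 2-fold none was called, and of 50 lowered 2-fold 10.0% were. The simulation changed most miRNAs detected on both arrays at once, many of them 4-fold, before normalization. Among those at least 50 units above the blanks, the median was −0.95 when lowered 4-fold and −1.08 when lowered 2-fold. The simulated rates here may thus differ from those on arrays with fewer changes. Brighter miRNAs were missed too: of those at least 50 units above the blanks, 0 of 11 raised 2-fold were called (median difference 0.28), while 62.5% of 8 lowered 2-fold, 66.7% of 12 raised 4-fold and 45.5% of 11 lowered 4-fold were. Blank subtraction with median scaling took the place of both normexp and quantile normalization. With it, 91 miRNAs were at least 2-fold higher and 107 at least 2-fold lower. However, all 198 of them read under 30 units above the blanks on both arrays. Blank subtraction left 128 of the 708 detected miRNAs without a value. The 198 were 34.1% of the 580 with one. Among simulated unchanged miRNAs, 42.9% of 483 with a value passed 2-fold. That simulated set had lost the changed miRNAs, all taken from those detected on both arrays, so the shares cannot be compared directly. Simulated 2-fold differences of miRNAs at least 50 units above the blanks were measured with the blanks subtracted at a median of 0.89 for 11 raised and −1.15 for 8 lowered, of which 18.2% and 87.5% passed 2-fold. Of the 98 observed miRNAs that read at least 30 units above the blanks on both arrays, a cut chosen after the data were seen, none was 2-fold apart with the blanks subtracted. There miR-93 again differed most (−0.70, spot error 0.13), at 0.614 of its control level.

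The miR-17~92 cluster and its paralogues, the clusters miR-106a to miR-363 and miR-106b~25, are known to promote proliferation and held 5 of the 7 lowest differences. Of 20 arms 19 were detected, of which 12 were lower, 5 higher and 2 equal, and 7 were lower and 0 higher by more than 2 spot errors. The list's median difference was −0.09, at percentile 0.765 of random lists of equal size and signal. The random lists were not matched on catalogue number. The 96 earliest-numbered miRNAs detected on both arrays, described below, had a median of −0.04. The 36 of them at least 30 units above the blanks had −0.11. Both sets include members of this list, so the percentile does not set the list apart from other earliest-numbered miRNAs. The lower members came from each cluster: miR-18a (difference −0.36, spot error 0.11) and miR-19a (−0.36, spot error 0.11) from miR-17~92, miR-18b from the miR-106a cluster, and miR-93 and miR-106b from miR-106b~25. Within each cluster the miRNA genes stand side by side in the human gene table (GRCh38.p14). It places 6 miRNA genes in the miR-17~92 span, 6 in that of miR-106a and 3 in miR-106b~25. With the blanks subtracted, 15 of the 18 members detected on both arrays were lower, 10 of them by more than 2 spot errors, and 3 were higher. The median depended on the setting: it was −0.061 with the mean of spot pixels, −0.20 with median scaling, −0.28 with the blanks subtracted and −0.35 in the deposited processed values. Near-identical arms such as miR-18a and miR-18b can share a probe's signal and are not independent values.

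miRNAs known to rise as erythroid cells mature did not stand apart. All 9 members of this list were detected on at least 1 array and 6 on both, with 2 higher, 6 lower and 1 equal, none by more than 2 spot errors. Their median was −0.05, at percentile 21.6 of random lists. miR-451, the dominant miRNA of red cells, read 675 units with control siRNA and 603 with ETO2 siRNA. Its difference was 0.00 (spot error 0.12), or −0.21 (spot error 0.13) with the blanks subtracted. The 0.00 reflects an equal rank on both arrays after quantile normalization. Over the 10 alternative settings the difference ran from −0.36, in the deposited processed values, to 0.00. miR-144, transcribed with miR-451, was near the detection limit at 37 and 38 units (difference 0.06, spot error 0.07). miR-486-5p differed by −0.11 (spot error 0.07) and miR-182 by −0.09 (spot error 0.07). miR-210, a hypoxia miRNA, and miR-144* were detected with control siRNA only, at 31 and 36 units.

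Of the 9 miRNAs known to be high in progenitors and to decline with erythroid maturation, 4 were detected, 3 lower and 1 higher, with a median of −0.17 at percentile 1.03. With the blanks subtracted, the 3 members detected on both arrays lay at percentile 5.14, inside the central 95% of random lists. The lower members were miR-103a, miR-223 (difference −0.29, spot error 0.07) and miR-126 (−0.05, spot error 0.07, and 0.015 with 75th percentile scaling). miR-221, which targets the KIT receptor, passed the limit with ETO2 siRNA only, at 33 units against 30 (difference 0.17, spot error 0.08). Its partner miR-222 read 27 units on each array and was detected on neither. miR-155 and miR-150 were not detected.

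Myeloid miRNAs had 5 of 7 members detected, all on both arrays, with 3 lower and 2 higher and a median of −0.09 at percentile 15.1. All 5 were lower with the blanks subtracted, with a median of −0.40 at percentile 7.04. miR-142-3p (difference −0.32, spot error 0.08) and miR-223, a granulocyte miRNA, were lower by more than 2 spot errors. miR-142-5p, from the other arm of the miR-142 hairpin, differed by 0.01 (spot error 0.07), and miR-21 by −0.09 (spot error 0.07). In the miR-30 family, 5 of 6 detected members were lower and 1 was higher, with a median of −0.11 at percentile 3.20. All 6 were lower with the blanks subtracted, with a median of −0.50 at percentile 2.80. Its largest differences were miR-30c at −0.23 (spot error 0.07) and miR-30d at −0.14 (spot error 0.07). Both have low catalogue numbers, on which the random lists were not matched. The miR-15/16 family divided: miR-16 was lower while miR-15b was higher, and miR-15a was at 0.14 (spot error 0.07). Its median was 0.14 over 5 detected members, at percentile 95.1. With the blanks subtracted it was −0.10 over the 4 members with a value, but 0.23 over the 3 detected on both arrays. It turned to −0.14 in the deposited processed values, where the median of all detected miRNAs with a value was itself −0.11. In the deposited values miR-15a itself stood at −0.14.

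**Figure D2:**
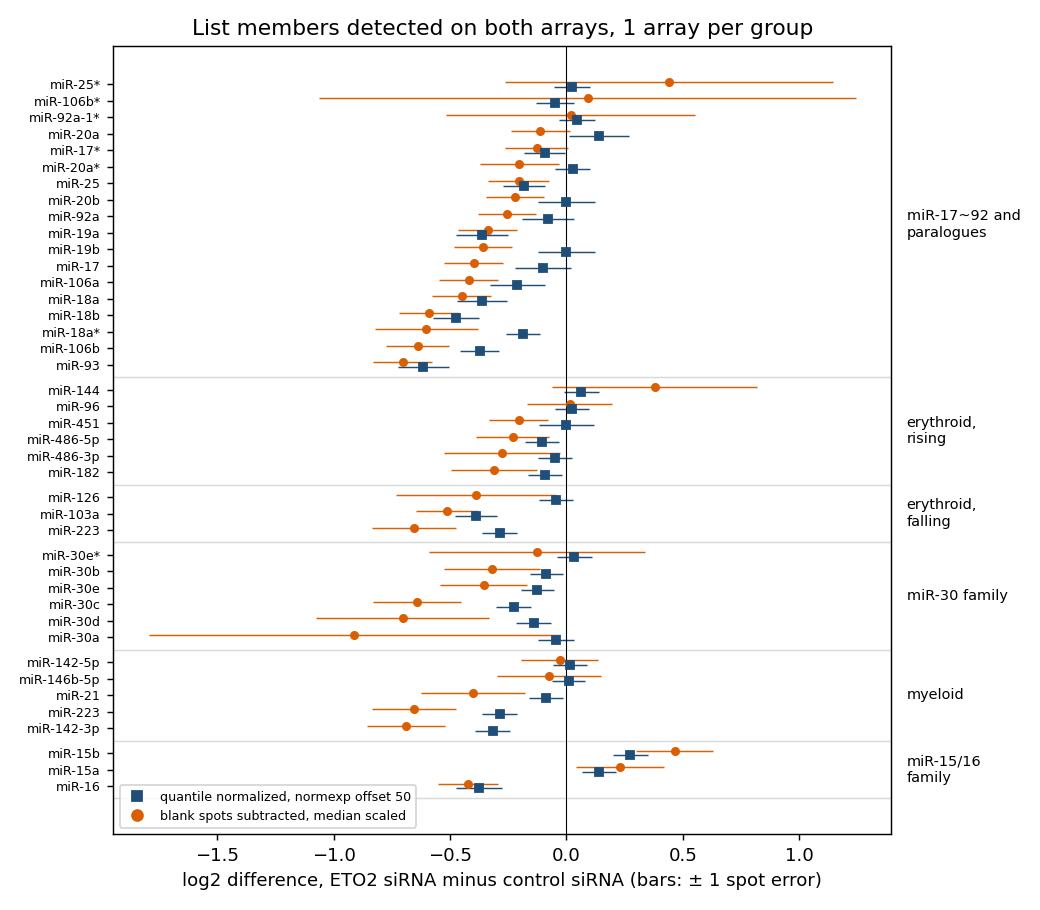
Log2 differences (ETO2 siRNA minus control siRNA, 1 array per group) of the members of 6 fixed lists that were detected on both arrays. Squares show the quantile-normalized values, circles those with the blank mean subtracted and median scaling, and bars ± 1 spot error. Most members of the miR-17~92 list lie below 0, led by miR-93 at −0.62 and −0.70, while miR-16 and miR-15b lie on opposite sides of 0; miR-20a lies above 0 in the first setting and below 0 in the second.

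The other lists of blood, stress and imprinted miRNAs with a median lay inside the central 95% of random lists. The miR-232724 clusters had 8 detected members and a median of −0.06, with miR-23b the largest at −0.22 (spot error 0.08). The let-7 family had 7 and a median of −0.02, near the limit throughout, with let-7a at −0.04 (spot error 0.07) and let-7c detected with ETO2 siRNA only. The miR-29 family had 3 and a median of −0.06. Megakaryocytic miRNAs had 5 and a median of −0.05, and the p53-induced list had 4 and a median of −0.06, with miR-107 at −0.19 (spot error 0.08). The lymphoid list had 2 detected members, miR-181a at −0.09 and miR-181b at 0.02, and the HOX-cluster list had miR-196b alone at −0.05, so no median is given for either. The imprinted DLK1-DIO3 region had 8 of 38 members detected and a median of 0.02, with miR-494 at −0.14 (spot error 0.08).

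Markers of other tissues were dim, with no detected member above 43 units on either array. The muscle list had 3 detected members, each on 1 array only, and a median of −0.23 at percentile 0.055, which turned to 0.46 with the blanks subtracted. Of these miR-499-5p read 43 units with control siRNA and 28 with ETO2 siRNA, and miR-133a read 28 and 34. The epithelial list had 3 detected members and a median of −0.05, and the mesenchymal list 5 and a median of 0.05, with miR-145 at 0.07 (spot error 0.08). miR-122* was the detected liver member, at −0.12, and the neuronal list had 2, miR-128 at 0.12 and miR-9* at 0.07.

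The control array alone detected 197 miRNAs and the ETO2 siRNA array alone 180. Of these 377 miRNAs, 314 differed by no more than the central 95% of the blank spots did. The blank spots were not quantile normalized and, unlike these miRNAs, not chosen by the detection limit. The brightest detected with control siRNA only was miR-499-5p, 1.24-fold higher there, followed by miR-3667-5p at 1.18-fold. By normalized signal, the brightest detected with ETO2 siRNA only were miR-548h, 1.18-fold higher there, and miR-431*, at least 1.17-fold higher. In scanner units miR-431* read 36 there, under miR-143* at 37. These ratios set the bright array's normalized signal against the higher of the dim array's lowest detected signal and the probe's own. For miR-499-5p, miR-3667-5p and miR-548h this gave the observed ratio, and for miR-431* a lower bound. None of them allows for spot error.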

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

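Spike control scaling, the mean of spot pixels and the joint settings were chosen after the data were seen, and the cause of the shifts below was not tested. No paired analysis was possible because each group has 1 array and the groups were not compared by a test across samples. Repeated spots taken singly were not run, since each miRNA has 1 spot. The count of 0 in each direction held under median, 75th percentile, cyclic loess, spike control and no scaling, without background correction, with the mean of spot pixels, under all 3 other detection filters and at 3-fold. At 1.5-fold 1 miRNA (miR-93) was lower and 0 were higher. The counts higher and lower were 91 and 107 with the blanks subtracted, 12 and 7 when these also had to be detected on both arrays, 55 and 51 with offset 0, and 12 and 15 in the deposited processed values. Detected miRNAs numbered 348 (control siRNA) and 334 (ETO2 siRNA) at 3 SD, and 212 and 225 at 5 SD, with 189 on both arrays at 5 SD, so signal over background limits what can be compared. Of detected miRNAs with a nonzero difference 51.8% were higher, against 61.3% with 75th percentile scaling, 40.8% with spike control scaling and 39.6% in the deposited values, whose median was itself −0.11 over the 439 detected miRNAs with a value on both arrays.

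List medians moved most where dim values were not drawn together. With the blanks subtracted they were −0.28 (erythroid rising), −0.45 (erythroid falling), −0.38 (miR-232724), −0.28 (miR-17~92), −0.50 (let-7), −0.78 (miR-29), −0.50 (miR-30), −0.40 (myeloid), −0.39 (megakaryocytic), −0.45 (p53), 0.80 (imprinted), −0.61 (epithelial) and 0.52 (mesenchymal), and changed sign for miR-15/16 (−0.10) and muscle (0.46); the epithelial value rests on 1 member and the muscle value on 2. Over miRNAs also detected on both arrays they were, in that order, −0.22, −0.51, −0.20, −0.30, −0.30, −0.55, −0.50, −0.40, −0.37, −0.45, −0.34, −0.61 and 0.56, with miR-15/16 at 0.23; here miR-29 and mesenchymal rest on 2 members each and epithelial on 1, too few for a list median. In the deposited processed values they were −0.34 (erythroid rising), −0.49 (erythroid falling), −0.33 (miR-232724), −0.35 (miR-17~92), −0.30 (let-7), −0.58 (miR-29), −0.46 (miR-30), −0.44 (myeloid), −0.40 (megakaryocytic), −0.60 (p53), −1.36 (muscle, 1 member) and 0.39 (mesenchymal, 2 members), and miR-15/16 changed sign (−0.14). With offset 0 they were −0.18 (erythroid rising), −0.36 (erythroid falling), −0.28 (miR-232724), 0.32 (miR-15/16), −0.25 (miR-29), −0.26 (miR-30), −0.23 (myeloid), −0.15 (megakaryocytic), −0.15 (p53), 0.11 (imprinted), −1.39 (muscle), −0.23 (epithelial) and 0.25 (mesenchymal). Without background correction they were −0.26 (erythroid falling), −0.15 (megakaryocytic), −0.16 (p53), −0.48 (muscle) and −0.13 (epithelial). The miR-17~92 median was −0.20 with median scaling, −0.19 with none and −0.22 on the spike controls. Without a detection filter the medians were −0.046 (erythroid falling), 0.025 (miR-15/16), 0.00 (muscle) and, with its sign changed, 0.009 (myeloid). Erythroid falling was −0.29 and imprinted −0.11 over miRNAs detected on both arrays and over the brighter of the detected miRNAs, where muscle was −0.057 with 2 members. Mesenchymal was −0.048 with the mean of spot pixels. The miR-17~92, miR-29, miR-30 and both erythroid medians were below 0 under every alternative run. Those of miR-232724, p53 and epithelial were too, except at 0.00 without a detection filter. Of 92 named miRNAs, 73 kept their sign under all settings that gave a value, 6 had a difference of 0, and 13 took another sign or 0 under at least 1. Those 13 were miR-9*, miR-29a, miR-143, let-7a, let-7b, let-7f, miR-181b, miR-126, miR-126*, miR-145, miR-142-5p, miR-15a and miR-27b*. Of them 2 differed by more than 1 spot error to begin with: miR-15a, at −0.14 in the deposited values, and miR-27b*, at 0.001 with the mean of spot pixels.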

Other observations

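The tests below were chosen only after the pattern was seen. The miRNAs lower with ETO2 siRNA carried mostly low catalogue numbers and those higher mostly high ones, so probes were divided into 4 equal groups by the number of their mature-sequence record. With the blanks subtracted, the 96 earliest-numbered miRNAs detected on both arrays had a median difference of −0.27 (72 lower, 24 higher), and the 73 latest-numbered a median of 0.09 (20 lower, 53 higher). The groups between them had medians of 0.09 (29 lower, 46 higher) and 0.03 (41 lower, 46 higher), so over this set the medians of the later 3 groups were not ordered by number. Among brighter miRNAs, at least 30 units above the blanks on both arrays, 33 of 36 earliest-numbered miRNAs were lower and 18 of 21 latest-numbered were higher, with 7 of 15 and 14 of 26 higher in the groups between. On the quantile-normalized scale the bright medians were −0.11 and 0.10, and those of the 96 and 73 miRNAs were −0.04 and 0.05. The median of the 73 latest-numbered miRNAs was 0.004 on the spike controls and turned to −0.06 in the deposited processed values, where that of the earliest was −0.35. The 21 brighter ones kept a median above 0 under both, at 0.11 each. The median of all detected miRNAs with a value was itself −0.04 on the spike controls and −0.11 in the deposited values. The sign of a group's median there thus depends on scaling.

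With the blanks subtracted, the gap between the earliest and the latest group was −0.37 (95% bootstrap interval over miRNAs, which are not replicates, −0.54 to −0.27); it was −0.09 (−0.13 to −0.04) on the quantile-normalized scale and −0.29 (−0.46 to −0.18) in the deposited values. A trend of the difference with signal would close it among miRNAs of like signal. Yet with the blanks subtracted it was −0.34 (−0.49 to −0.18) within 5 bins of mean signal. After subtracting the median of each of the 16 printing blocks the gap was −0.38 (−0.54 to −0.26). That argues against shifts between whole blocks, but a trend within blocks would pass this subtraction and was not tested. Lower miR-17~92 clusters alone do not account for the gap either. The 82 earliest-numbered miRNAs outside that list had a median of −0.23 (−0.34 to −0.14) against 0.09 for the latest group. Of these 82, 58 were lower. On the quantile-normalized scale the medians were −0.02 (−0.06 to 0.00) and 0.05. The miR-17~92 list may therefore be part of a wider shift of long-known miRNAs relative to later-numbered ones. The same may hold for the miR-30 and erythroid-falling lists, whose detected members named above were earliest-numbered too. GC content of the probes, the wash of either array, the share of miRNA in the labelled RNA, and an effect of ETO2 siRNA on miRNA levels stay open, untested here because probe sequences were not used and each group has 1 array.

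miR-15a and miR-15b stood at 0.23 and 0.46 with the blanks subtracted (spot errors 0.19 and 0.16), while miR-16, which is transcribed with each of them, stood at −0.42 (spot error 0.13). miR-142-3p and miR-142-5p, the arms of one hairpin, stood at −0.69 (spot error 0.17) and −0.03 (spot error 0.17).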
